A study of Rattus norvegicus with 35 samples.

How the data were processed

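RNA of the cardiac left ventricle of male Wistar rats was measured on 35 Illumina BeadChip arrays, 6 per group (5 for ligated animals at day 6). Per the labels, the tissue was kept in RNAlater, total RNA was extracted with a Qiagen RNeasy Fibrous Tissue Mini kit, amplified with the Illumina TotalPrep kit and labelled with Cy3, and BeadStudio 3.30 and GenomeStudio (version not stated) processed the scans. The labels do not state which step each program did. Groups and replicates were taken from the labels. All arrays of a day lie on 1 BeadChip, so day and BeadChip cannot be told apart, and sham groups were not compared across days. At days 1 and 42 the ligated arrays lie at positions A to F and the sham arrays at G to L, so that position and operation cannot be separated there, whereas at day 6 both operations lie in both sets of positions.

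The deposited table of each day holds, per the file headers, 4 columns per array, of which 3 were used: the scanner intensity of each probe averaged over its beads, a detection p-value against the negative control beads, and, as an other kind of value, the number of beads. The standard error over beads was not used here. From the values, the intensity was neither normalised nor background-subtracted, since it is above 0 throughout and its medians differ between arrays. The deposited series matrix holds intensity on a linear scale that the authors background-subtracted and normalised by a method that the labels do not state. Its values include some below 0, rank the probes of an array as the scanner intensity does, and share a median within each day of 15.7 at day 1, 25.5 at day 6 and 21.4 at day 42, from which a normalisation within each day was inferred. The scanner intensity was used as the main source and the series matrix as an alternative. In the table of day 6, 1 array (4 columns) matches no sample and was not used here.

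Each table has 22523 probes, of which 13793 have a gene symbol in the probe annotation supplied with the series and 8730 have none. The latter count among probes tested but were not named. Intensities of each day were background-corrected with the normexp model of limma, with the mean and spread of the negative controls inferred from the detection p-values (offset 16), quantile-normalised within the day and log2-transformed. Probes were kept with a detection p under 0.01 in at least 5 arrays of the day. Bead arrays give no count depth. The median number of beads per probe lay between 30 and 42 per array, and the number of arrays limits the precision.

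Ligated and sham arrays were compared within each day with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with p-values adjusted by Benjamini-Hochberg over all probes tested and a threshold of 0.05. Differences of the ligation effect between days came from 1 fit of the 6 group means over all 35 arrays. The days share no animals or controls. For genes with several probes, the probe with the highest mean intensity of the day stands for the gene. A probe detected on no array of a group is given as a lower bound, with each array of that group set to no less than the lowest level detected on it. Gene lists, 18 of pathways and 14 of cell type markers, were tested with camera (preset correlation 0.01, lists with at least 3 measured genes, adjusted over the lists of the day), which compares a list with all other genes. Further tests were run as alternatives. The first was camera with the correlation estimated per list. The second was fry, whose p-value tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Similarity of days was measured by the correlation of log2 fold changes across probes and by shared calls against the number expected from independent calls, with no p-value since probes are not independent. Array brightness and the share of probes detected were compared with two-sided exact permutation tests.

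Lists, comparisons, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule names, per day, the 8 genes with the largest rises and the 8 with the largest falls that passed and were detected on all arrays of a group, up to 4 members with the smallest p of each list that passed or had a member that passed, and 12 fixed genes (Nppa, Nppb, Myh6, Myh7, Acta1, Ankrd1, Atp2a2, Col1a1, Col3a1, Postn, Timp1 and Ctgf, now Ccn2). For each difference between days it names the 6 largest. From these, members of lists were selected for the text to illustrate each list.

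The alternatives were no background correction, median scaling, normalisation of all 35 arrays together, the series matrix values, no detection filter, detection in every array, a spread shared by all 6 groups, eBayes with trend and robust, array weights, a replicate block, a block for BeadChip position at day 6, each array left out in turn, and, added after the data had been seen, array brightness as a covariate. Median scaling made the median over all 22523 probes equal between arrays. At most 40.3% of them were detected on an array, so it need not remove differences in array brightness. Where the text counts alternative fits of a gene, each array left out is 1 of them. Figures were drawn with matplotlib 3.10.9.

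The procedure was tested on simulated data made on the probes of each table with known fold changes. Per comparison of ligated with sham, changes of 1.5-, 2- and 4-fold were recovered in 49.3%, 95.5% and 95.5% of changed probes at day 1, 32.8%, 79.1% and 95.5% at day 6, and 53.7%, 88.1% and 100% at day 42, with 3 of 163, 11 of 149 and 12 of 173 calls false. For differences between days, 2-fold changes were recovered in 81.4% (days 1 and 6), 74.0% (days 6 and 42) and 78.0% (days 1 and 42), and the share of false calls was 11.3%, 7.48% and 6.38%, above the nominal 5%. The shares of false calls within day 6 (7.38%) and day 42 (6.94%) were above it too. A simulated 1.5-fold rise of the matrix list was called by camera, by camera with an estimated correlation and by fry on each day, with 0 other lists called. The simulated noise was independent between probes, and the simulated signals held no difference in brightness between the operations. These runs therefore do not show how often lists are called falsely where genes vary together. Nor do they give the share of false probe calls in the real data, where array brightness differed and probes vary together.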

Results

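Gene expression in the cardiac left ventricle of male Wistar rats was measured 1, 6 and 42 days after the abdominal aorta was ligated, an operation that raises the pressure load on the heart, and after a sham operation. Each of the 6 groups held 6 arrays, apart from the ligated animals at day 6 with 5, so that 35 arrays were compared. Each array carried 22523 probes, of which 13793 had a gene symbol, covering 13337 genes. Between 32.8% and 40.3% of the probes of an array were detected above its negative controls. The number of arrays limits the precision of all values, which are log2 fold changes of ligated over sham ± standard error (SE) unless another unit is given.

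The brightness of the arrays before scaling, taken as the 75th percentile of the scanner signal, differed between the operations on the last day. At day 42 it was 206 ± 36.9 intensity units (SD, n = 6) in the ligated and 293 ± 30.5 (SD, n = 6) in the sham arrays (two-sided exact permutation p = 0.00433). The means were 254 and 219.6 at day 1 (two-sided exact permutation p = 0.104) and 279.8 and 268 at day 6 (two-sided exact permutation p = 0.762). The share of probes detected was 2.19 percentage points higher in the ligated arrays at day 1 (two-sided exact permutation p = 0.0303), 0.683 higher at day 6 (two-sided exact permutation p = 0.528) and changed by -3.00 at day 42 (two-sided exact permutation p = 0.00866). At days 1 and 42 the ligated arrays lay at positions A to F of the BeadChip and the sham arrays at G to L, so that position cannot be separated from the operation there.

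**Figure D1:**
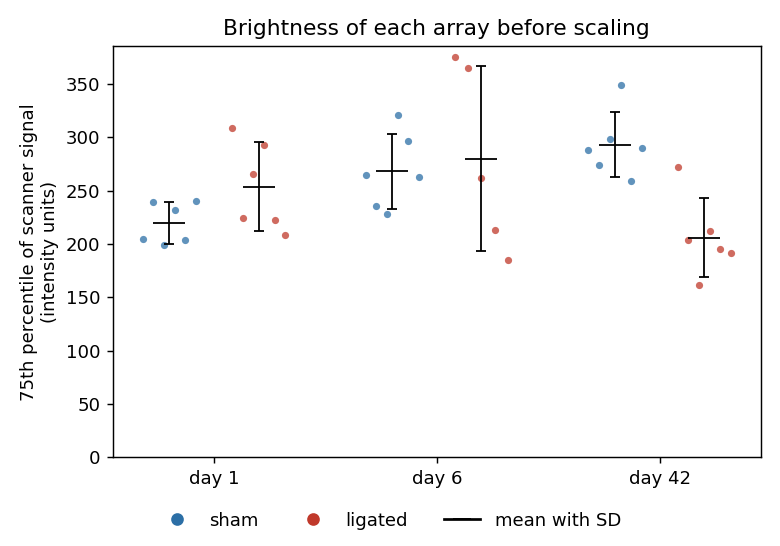
The 75th percentile of the scanner signal (intensity units) of each array is plotted by day, with sham arrays in blue, ligated arrays in red, and each group's mean and SD in black. At day 42 the ligated arrays averaged 206 and the sham arrays 293 intensity units.

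The comparison of ligated with sham ventricles at day 1 addressed the early response to the operation. More genes rose than fell in lists of the extracellular matrix, the cardiac stress programme, inflammation and protein folding, and more fell than rose in lists of energy metabolism (n = 6 per group). With an estimated correlation 0 lists passed on this day, the lowest adjusted p being 0.103. Spp1, which encodes the matrix-associated cytokine osteopontin, rose 28.5-fold (4.83 ± 1.07, adjusted p = 0.00609). It was detected on 6 of 6 ligated and 3 of 6 sham arrays. Reg3b, a secreted lectin of the acute response, rose 17.1-fold (4.10 ± 0.62, adjusted p = 0.000944), with every ligated array above every sham array. Apln, which encodes the peptide hormone apelin, was 3.82-fold lower (-1.94 ± 0.23, adjusted p = 0.000387), again with no overlap between the groups. In all, 803 genes rose and 1008 fell among 6218 tested. Of these, 142 rose and 60 fell by 2-fold or more.

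**Figure D2:**
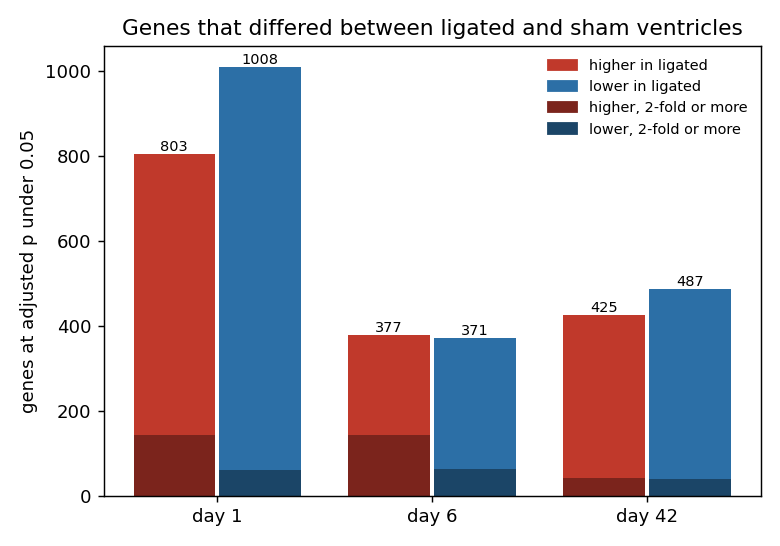
Bars give the number of genes (y axis) that were higher or lower in ligated than in sham ventricles at each day (adjusted p under 0.05), the darker parts those that changed 2-fold or more. The counts were 803 and 1008 at day 1, 377 and 371 at day 6, and 425 and 487 at day 42, and under median scaling most calls rose at day 1 and fell at day 42.

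Of the 47 measured genes of the extracellular matrix and fibrosis, 25 rose and 3 fell (28 and 4 adjusted over the list alone, 26 and 0 under median scaling). Matrix genes as a list had adjusted p = 4.91e-07, and adjusted p = 0.468 with an estimated correlation. After Spp1 the largest rises were in Timp1, an inhibitor of matrix metalloproteinases (9.44-fold, 3.24 ± 0.35), and Ltbp2, a protein of elastic microfibrils (8.67-fold, 3.12 ± 0.50). Ltbp2 was detected on 6 of 6 ligated and 1 of 6 sham arrays. Postn, the matricellular protein periostin, rose 7.94-fold (2.99 ± 0.51) and Thbs4, a thrombospondin, 6.74-fold (2.75 ± 0.51). The growth factor Tgfb2 (2.12 ± 0.27) and the connective tissue growth factor Ccn2 (1.42 ± 0.29) rose as well. The fibrillar collagen Col1a1 was at 0.51 ± 0.25 (adjusted p = 0.131, passing in 2 of 23 alternative fits). Its partner Col3a1 was at -0.05 ± 0.25 (adjusted p = 0.903), and above 0 under median scaling.

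Of the 18 inflammatory cytokines and acute phase genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone, 12 and 0 under median scaling). Inflammatory genes as a list had adjusted p = 0.000625, and adjusted p = 0.468 with an estimated correlation. The monocyte chemokine Ccl2 rose 7.40-fold (2.89 ± 0.50, detected on 6 of 6 ligated and 3 of 6 sham arrays). Its relative Ccl7 was at least 4.85-fold higher (detected on 5 of 6 ligated and 0 of 6 sham arrays). The neutrophil chemokine Cxcl1 rose by 1.30 ± 0.26 (detected on 6 of 6 ligated and 2 of 6 sham arrays). Hamp, the iron hormone hepcidin, rose 6.36-fold (2.67 ± 0.45). Macrophage markers moved with the matrix and inflammatory genes, as 5 rose and 0 fell (6 and 0 adjusted over the list alone, 7 and 0 under median scaling) among 14. They had adjusted p = 0.00151, and adjusted p = 0.468 with an estimated correlation. Examples were Cd14 (1.42 ± 0.31), Tyrobp (1.29 ± 0.30) and Lgals3 (1.53 ± 0.39). Among 5 Schwann and nerve markers, 4 rose and 0 fell (5 and 0 adjusted over the list alone, 5 and 0 under median scaling). Schwann and nerve markers had adjusted p = 0.00182, and adjusted p = 0.414 with an estimated correlation. Cnp, a myelin enzyme, rose by 0.65 ± 0.10 and Gap43, a protein of growing axons, by 1.03 ± 0.29.

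Among the 13 stress and fetal cardiac genes, 8 rose and 0 fell (11 and 0 adjusted over the list alone, 11 and 0 under median scaling). Stress genes as a list had adjusted p = 3.54e-06, and adjusted p = 0.103 with an estimated correlation. Enah, an actin regulator (1.46 ± 0.13), Flnc, an actin crosslinker of the Z disc (1.68 ± 0.23), and Csrp3, a muscle LIM protein (0.85 ± 0.11), rose. Nppa, the atrial natriuretic peptide, rose by 1.39 ± 0.39 and Ankrd1, a stress-responsive muscle ankyrin repeat protein, by 0.30 ± 0.09. Nppb, the B-type natriuretic peptide, was at 0.34 ± 0.14 (adjusted p = 0.0798, passing in 2 of 23 alternative fits). The skeletal actin Acta1 was at 0.55 ± 0.20 (adjusted p = 0.0535, passing in 7 of 23 alternative fits) and the fetal myosin Myh7 at 0.36 ± 0.18 (adjusted p = 0.147). The probes of Ankrd1, Myh7, Myh6 and Atp2a2 on every day, and of Acta1 and Uqcrb at day 6, had a mean log2 scanner intensity between 15.07 and 16.02. That is near the upper end of the scanner range, where a change can be compressed, so a small value there does not show that a gene did not change. The call of Ankrd1 was lost in the series matrix values. Of the 26 genes of the heat shock and unfolded protein response, 16 rose and 1 fell (18 and 1 adjusted over the list alone, 17 and 0 under median scaling). Heat shock genes as a list had adjusted p = 6.41e-06, and adjusted p = 0.468 with an estimated correlation. The endoplasmic reticulum chaperones Hspa5 (0.87 ± 0.13) and Hsp90b1 (1.01 ± 0.16) and the small heat shock protein Hspb1 (1.53 ± 0.25) were among those that rose.

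Of 22 immediate early genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone, 8 and 0 under median scaling). Immediate early genes as a list had adjusted p = 0.0129, and adjusted p = 0.468 with an estimated correlation. The transcription factors Myc (1.85 ± 0.29) and Junb (1.24 ± 0.27) rose, and Fos was at least 1.65-fold higher (detected on 5 of 6 ligated and 0 of 6 sham arrays). Of 15 cell cycle genes, 4 rose and 0 fell (13 and 0 adjusted over the list alone, 6 and 0 under median scaling). Cell cycle genes as a list had adjusted p = 5.21e-05, and adjusted p = 0.468 with an estimated correlation. The replication helicase subunits Mcm6 (1.55 ± 0.32) and Mcm2 (1.06 ± 0.24) were among them. Of 26 ribosome biogenesis genes, 8 rose and 2 fell (9 and 2 adjusted over the list alone, 14 and 1 under median scaling). Ribosome biogenesis as a list had adjusted p = 0.00215, and adjusted p = 0.510 with an estimated correlation. Nop58, a nucleolar protein, rose by 0.76 ± 0.16, and Polr1a, the large subunit of RNA polymerase I, changed by -0.76 ± 0.13.

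In energy metabolism more genes fell than rose. Of 36 fatty acid oxidation genes, 1 rose and 17 fell (1 and 19 adjusted over the list alone, 1 and 5 under median scaling). Fatty acid oxidation as a list had adjusted p = 0.000625, and adjusted p = 0.510 with an estimated correlation. The mitochondrial beta-oxidation enzymes Hadh (-0.89 ± 0.19) and Hadhb (-0.49 ± 0.11) fell, Hadhb with its call lost under median scaling. The member that rose was Angptl4, a secreted inhibitor of lipoprotein lipase (at least 2.99-fold higher, detected on 6 of 6 ligated and 0 of 6 sham arrays). Of 43 genes of the TCA cycle and oxidative phosphorylation, 1 rose and 24 fell (2 and 26 adjusted over the list alone, 2 and 2 under median scaling). TCA cycle genes as a list had adjusted p = 6.26e-06, and adjusted p = 0.468 with an estimated correlation. The complex I and II subunits Ndufs1 (-0.60 ± 0.11) and Sdhb (-0.44 ± 0.10) fell, both with the call lost under median scaling, and the coactivator Ppargc1b rose (0.84 ± 0.12). Of 19 genes of glucose uptake and glycolysis, 0 rose and 11 fell (2 and 14 adjusted over the list alone, 4 and 4 under median scaling). Glycolysis genes as a list had adjusted p = 0.00294, and adjusted p = 0.468 with an estimated correlation. The insulin-responsive transporter Slc2a4 (-1.18 ± 0.20) and the hexokinase Hk2 (-0.74 ± 0.18) fell, Hk2 with its call lost under median scaling.

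Of 25 genes of calcium handling and ion channels, 1 rose and 7 fell (1 and 7 adjusted over the list alone, 1 and 2 under median scaling). Calcium handling as a list had adjusted p = 0.0457, and adjusted p = 0.510 with an estimated correlation. Hrc, a calcium-binding protein of the sarcoplasmic reticulum, fell 2.65-fold (-1.40 ± 0.30), and the potassium channel subunits Kcnj11 (-0.74 ± 0.20) and Kcnip2 (-0.79 ± 0.23, its call lost under median scaling) fell too. Atp2a2, the calcium pump, near the upper end of the range, was at 0.05 ± 0.08 (adjusted p = 0.655), and below 0 in the series matrix values. The adult myosin Myh6 was at -0.14 ± 0.14 (adjusted p = 0.454), and above 0 under median scaling. Outside the lists, Kcnk2, a mechanically gated potassium channel, fell 3.45-fold (-1.78 ± 0.23) and Gpcpd1, a phosphodiesterase of lipid metabolism, 3.12-fold (-1.64 ± 0.20). Fam81a fell 2.93-fold (detected on 2 of 6 ligated and 6 of 6 sham arrays). Bola3, an iron-sulfur cluster factor, fell 2.83-fold, Gcgr, the glucagon receptor, 2.69-fold and Asb10 2.68-fold.

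By probe, 2368 of 8236 passed in limma, 1082 up and 1286 down (45.7% up). Median scaling moved the median of all probes to 0.20 and gave 2042 calls, 83.9% of them up. Before scaling, the ligated arrays were brighter than the sham arrays by a similar 0.198 log2 units. The count was 1199 with array brightness in the fit, in which Nppa, Tyrobp, Lgals3, Gap43, Mcm2, Kcnj11 and Kcnip2 lost their calls, and 1576 without ligated replicate 4. With no detection filter Nppa, Gap43 and Kcnip2 lost theirs.

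**Figure D3:**
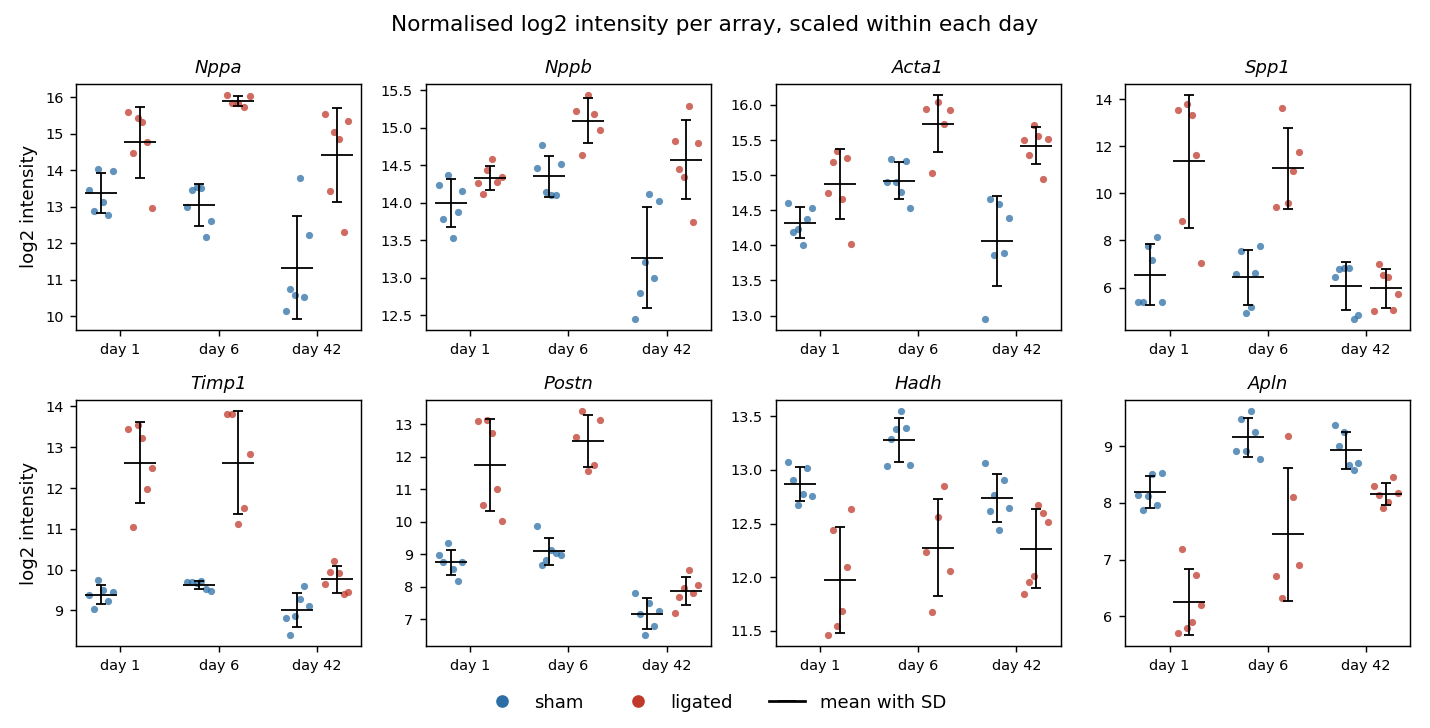
Each panel plots the normalised log2 intensity of a gene on each array (y axis) by day (x axis), sham in blue and ligated in red, with the mean and SD of each group in black. Scaling was done within each day, so levels are not compared between days. Nppa changed by 1.39, 2.86 and 3.10 log2 units at days 1, 6 and 42, and Timp1 by 3.24, 2.99 and 0.75.

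The comparison at day 6 addressed the response between the early and the late time point. More genes rose than fell in lists of the matrix, the cardiac stress programme, the cell cycle and macrophages, and more fell than rose in those of fatty acid oxidation and ion channels (n = 5 ligated and 6 sham). With an estimated correlation 1 list passed, that of the stress genes (adjusted p = 0.00525). Reg3b rose 77.7-fold (6.28 ± 0.46, adjusted p = 2.48e-05) and Spp1 24.9-fold (4.64 ± 0.73, adjusted p = 0.00327, detected on 5 of 5 ligated and 4 of 6 sham arrays). Thbs4 rose 15.0-fold (3.90 ± 0.36, adjusted p = 7.78e-05) and Nppa 7.25-fold (2.86 ± 0.23, adjusted p = 2.64e-05). None of these 4 genes had overlapping groups. In all, 377 genes rose and 371 fell among 6404 tested, with 142 rises and 63 falls of 2-fold or more.

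Of 13 stress and fetal cardiac genes, 8 rose and 0 fell (9 and 0 adjusted over the list alone, 2 and 0 under median scaling). Stress genes as a list had adjusted p = 5.18e-08, and adjusted p = 0.00525 with an estimated correlation, the only list of the 3 days that passed both tests. Nppb (0.74 ± 0.17), Acta1 (0.81 ± 0.19), Flnc (1.30 ± 0.14) and Tubb6, a beta tubulin (1.51 ± 0.25), rose beside Nppa. Under median scaling Nppb, Acta1 and Tubb6 lost their calls. Myh7 was at 0.21 ± 0.17 (adjusted p = 0.458) and Ankrd1 at 0.27 ± 0.11 (adjusted p = 0.141, passing in 1 of 23 alternative fits), both near the upper end of the scanner range. Ankrd23, another muscle ankyrin repeat protein, rose 8.50-fold (3.09 ± 0.24, detected on 5 of 5 ligated and 2 of 6 sham arrays). Mybpc2, the fast skeletal myosin-binding protein C, rose 7.99-fold (SE 0.35 on the log2 scale).

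Of 47 matrix genes, 22 rose and 0 fell (25 and 0 adjusted over the list alone, 10 and 0 under median scaling). Matrix genes as a list had adjusted p = 1.30e-13, and adjusted p = 0.218 with an estimated correlation. Ltbp2 rose 10.8-fold (3.44 ± 0.31, detected on 5 of 5 ligated and 3 of 6 sham arrays) and Cthrc1, a secreted collagen triple helix protein, 9.35-fold (3.22 ± 0.34, detected on 5 of 5 ligated and 3 of 6 sham arrays). Postn rose 10.5-fold (3.39 ± 0.32), Timp1 7.97-fold (2.99 ± 0.43) and Ccn2 2.17-fold (1.12 ± 0.21). Col1a1 rose by 1.09 ± 0.26 (adjusted p = 0.0216), and Col3a1 was at 0.42 ± 0.34 (adjusted p = 0.437). Col1a1 and Ccn2 did not pass under median scaling. Fibroblast markers moved with the matrix genes, as 3 rose and 0 fell (3 and 0 adjusted over the list alone, 1 and 0 under median scaling) of 14. They had adjusted p = 0.00897, and adjusted p = 0.350 with an estimated correlation. Besides Col1a1, the calcium-binding protein S100a4 (2.12 ± 0.35) and the microfibril protein Mfap5 (1.10 ± 0.24, its call lost under median scaling) were the members that rose.

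Of 21 cell cycle genes, 12 rose and 0 fell (17 and 0 adjusted over the list alone, 2 and 0 under median scaling). Cell cycle genes as a list had adjusted p = 1.06e-09, and adjusted p = 0.276 with an estimated correlation. Examples were the mitotic cyclin Ccnb2 (2.13 ± 0.40), the kinase Cdk1 (2.05 ± 0.46), the ubiquitin-conjugating enzyme Ube2c (1.78 ± 0.34) and Mcm6 (1.08 ± 0.24). Ube2c was detected on 5 of 5 ligated and 2 of 6 sham arrays, and Cdk1 and Mcm6 did not pass under median scaling. Macrophage markers moved with the cell cycle genes, as 11 rose and 0 fell (14 and 0 adjusted over the list alone, 1 and 0 under median scaling) of 15. They had adjusted p = 2.73e-09, and adjusted p = 0.276 with an estimated correlation. The complement gene C1qc (1.37 ± 0.25), the mannose receptor Mrc1 (1.66 ± 0.34) and the galectin Lgals3 (4.01-fold) were among them, C1qc and Mrc1 with their calls lost under median scaling. Of 19 inflammatory and acute phase genes, 9 rose and 0 fell (12 and 0 adjusted over the list alone, 3 and 0 under median scaling). Inflammatory genes as a list had adjusted p = 2.63e-07, and adjusted p = 0.276 with an estimated correlation. Lbp, which binds bacterial lipopolysaccharide (2.12 ± 0.31), Hmox1, the haem oxygenase (2.56 ± 0.44), and the cytokine-activated factor Stat3 (0.73 ± 0.14, its call lost under median scaling) rose.

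Of 24 antioxidant genes, 5 rose and 0 fell (8 and 1 adjusted over the list alone, 2 and 0 under median scaling). Antioxidant genes as a list had adjusted p = 0.0282, and adjusted p = 0.276 with an estimated correlation. Gclc, which makes glutathione (0.90 ± 0.13), and Hmox1 were among the rises. Of the genes named in this paragraph only Hmox1 passed under median scaling. Of 26 heat shock and unfolded protein response genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone, 0 and 0 under median scaling). Heat shock genes as a list had adjusted p = 0.00310, and adjusted p = 0.157 with an estimated correlation. The rises included Hspb1 (0.86 ± 0.18) and Hspb7 (0.67 ± 0.13). Of 22 immediate early genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone, 0 and 0 under median scaling). Immediate early genes as a list had adjusted p = 0.0165, and adjusted p = 0.568 with an estimated correlation. The transcription factors Atf3 (1.15 ± 0.23) and Junb (1.57 ± 0.42, its call lost in 10 of 23 alternative fits) rose. Of 26 ribosome biogenesis genes, 4 rose and 0 fell (5 and 0 adjusted over the list alone, 0 and 0 under median scaling). Ribosome biogenesis as a list had adjusted p = 0.00201, and adjusted p = 0.276 with an estimated correlation. The nucleolar proteins Ncl (0.53 ± 0.11) and Npm1 (0.60 ± 0.14) rose. Of 5 Schwann and nerve markers, 1 rose and 0 fell (1 and 0 adjusted over the list alone, 0 and 0 under median scaling). These markers had adjusted p = 0.0282, and adjusted p = 0.276 with an estimated correlation. The rise was in Dbh, which makes noradrenaline (0.72 ± 0.21), a call lost in 13 of 23 alternative fits. Of 3 mast cell markers, 0 rose and 1 fell (0 and 2 adjusted over the list alone, 0 and 0 under median scaling). Mast cell markers had adjusted p = 0.0453, and adjusted p = 0.276 with an estimated correlation. The fall was in the tryptase Tpsb2 (-1.07 ± 0.25, detected on 1 of 5 ligated and 5 of 6 sham arrays).

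Of 35 fatty acid oxidation genes, 0 rose and 13 fell (1 and 21 adjusted over the list alone, 0 and 2 under median scaling). Fatty acid oxidation as a list had adjusted p = 4.11e-08, and adjusted p = 0.276 with an estimated correlation. Hadh (2.01-fold lower) and the acyl-CoA synthetases Acsl1 (-0.72 ± 0.14) and Acsl6 (-1.25 ± 0.25) fell, Acsl1 with its call lost under median scaling. Of 21 genes of calcium handling and ion channels, 0 rose and 6 fell (0 and 8 adjusted over the list alone, 0 and 4 under median scaling). Calcium handling as a list had adjusted p = 0.000296, and adjusted p = 0.218 with an estimated correlation. Trdn, a partner of the ryanodine receptor (-1.37 ± 0.15), the potassium channel Kcnd3 (-1.01 ± 0.15, detected on 3 of 5 ligated and 6 of 6 sham arrays) and the sodium channel subunit Scn4b (-1.29 ± 0.24) fell. Of 43 TCA cycle and oxidative phosphorylation genes, 1 rose and 4 fell (1 and 9 adjusted over the list alone, 0 and 0 under median scaling). TCA cycle genes as a list had adjusted p = 2.84e-06, and adjusted p = 0.460 with an estimated correlation. Uqcrb, a complex III subunit (-0.45 ± 0.11), and Sucla2, a succinate-CoA ligase subunit (-0.67 ± 0.17), fell, and Idh3b, an isocitrate dehydrogenase subunit (0.61 ± 0.13), rose. All 3 lost their calls under median scaling, and Sucla2 in 8 of 23 alternative fits. Of 19 glycolysis genes, 1 rose and 4 fell (1 and 5 adjusted over the list alone, 0 and 1 under median scaling). They did not pass as a list, with adjusted p = 0.0549, and adjusted p = 0.568 with an estimated correlation. The muscle enolase Eno3 fell 3.24-fold (-1.70 ± 0.28).

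Atp2a2 was at -0.06 ± 0.09 at day 6 (adjusted p = 0.707), and above 0 in the series matrix values, and Myh6 at 0.09 ± 0.15 (adjusted p = 0.714), both near the upper end of the range. The largest falls were in Fam81a (4.44-fold, detected on 1 of 5 ligated and 6 of 6 sham arrays), Kcnk2 (3.88-fold, -1.95 ± 0.27) and Apln (3.27-fold, -1.71 ± 0.42). Igsf1 fell 3.10-fold, Pdia2, a protein disulfide isomerase, 3.04-fold and Gpt, an alanine aminotransferase, 2.86-fold. Fxyd3, a regulator of the sodium pump, fell 3.04-fold (detected on 4 of 5 ligated and 6 of 6 sham arrays), a call lost in 8 of 22 alternative fits.

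By probe, 958 of 8492 passed in limma, 458 up and 500 down. A block for the BeadChip position (A to F against G to L), which mixes ligated and sham on this day, gave 1197. Median scaling gave 132 calls (50 up and 82 down), no detection filter 562 (Apln, Tpsb2 and Col1a1 among the calls lost), a replicate block 315 (Nppb, Acta1, Col1a1, Apln, Cdk1 and Ube2c among those lost) and a spread shared by all 6 groups 1634. Leaving out ligated replicate 2 or 5 or sham replicate 1, 2, 4, 5 or 6 gave between 524 and 627.

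The comparison at day 42 addressed the late response to the ligation. The natriuretic peptides, skeletal actin and 11 of 46 matrix genes rose, and 11 of 34 fatty acid oxidation genes and several cytotoxic lymphocyte transcripts fell (n = 6 per group). The cytotoxic lymphocyte transcripts were grouped only after their values had been seen. With an estimated correlation 0 lists passed on this day, the lowest adjusted p being 0.266. The ligated arrays were also the dimmer ones. Nppa rose 8.56-fold (3.10 ± 0.66, adjusted p = 0.00945), Nppb 2.47-fold (1.31 ± 0.30, adjusted p = 0.0140) and Acta1 2.57-fold (1.36 ± 0.25, adjusted p = 0.00469). Cyp2e1, a cytochrome P450 of ethanol and ketone metabolism, was 5.70-fold lower (-2.51 ± 0.32, adjusted p = 0.000624, detected on 1 of 6 ligated and 6 of 6 sham arrays). In all, 425 genes rose and 487 fell among 6229 tested, with 41 rises and 40 falls of 2-fold or more.

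Of 13 stress and fetal cardiac genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone, 6 and 0 under median scaling). Stress genes as a list had adjusted p = 3.18e-05, and adjusted p = 0.266 with an estimated correlation. Enah (1.25 ± 0.21), Csrp3 (0.52 ± 0.10) and the calcineurin regulator Rcan1 (0.86 ± 0.17) rose beside the natriuretic peptides and Acta1, Csrp3 and Rcan1 with their calls lost under median scaling. Myh7 was at 0.61 ± 0.29 (adjusted p = 0.152, passing in 1 of 23 alternative fits) and Ankrd1 at 0.32 ± 0.11 (adjusted p = 0.0651, passing in 7 of 23 alternative fits), both near the upper end of the scanner range. Of 46 matrix genes, 11 rose and 1 fell (14 and 1 adjusted over the list alone, 5 and 13 under median scaling). Matrix genes as a list had adjusted p = 0.00294, and adjusted p = 0.479 with an estimated correlation. Their median change of 0.23 was -0.27 under median scaling, or 0.21 relative to all genes. Col8a1, a short-chain collagen (1.41 ± 0.16), the proteoglycan Bgn (0.85 ± 0.13), Tgfb2 (1.65 ± 0.27) and Ltbp2 (1.61 ± 0.27, detected on 6 of 6 ligated and 2 of 6 sham arrays) rose. So did Ccn2 (1.52 ± 0.33) and Timp1 (0.75 ± 0.20), and Col3a1 fell (-0.57 ± 0.18, adjusted p = 0.0485), a call lost in 16 of 23 alternative fits. Bgn and Timp1 did not pass under median scaling. Postn was at 0.70 ± 0.23 (adjusted p = 0.0547, passing in 6 of 23 alternative fits). Col1a1 was at 0.06 ± 0.22 (adjusted p = 0.886), and below 0 under median scaling.

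Other large rises were in Ankrd23 (4.82-fold, 2.27 ± 0.40, detected on 6 of 6 ligated and 3 of 6 sham arrays) and Sec61g, a subunit of the protein translocation channel (4.16-fold, 2.06 ± 0.34, detected on 6 of 6 ligated and 3 of 6 sham arrays). Vash2, an angiogenesis regulator, rose 3.73-fold, Samd12 3.34-fold and Sbsn 3.81-fold, each detected on 6 of 6 ligated and 5 of 6 sham arrays. The call of Sbsn was lost in 8 of 22 alternative fits. Akip1, a protein kinase A partner, rose 3.61-fold and the small GTPase Rnd1 3.41-fold. Vegfa, an angiogenic growth factor, rose by 1.00 ± 0.16 and Ddit3, a transcription factor of endoplasmic reticulum stress, by 0.71 ± 0.11, a call lost under median scaling.

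Of 34 fatty acid oxidation genes, 0 rose and 11 fell (1 and 19 adjusted over the list alone, 0 and 30 under median scaling). Fatty acid oxidation as a list had adjusted p = 5.95e-06, and adjusted p = 0.266 with an estimated correlation. The beta-oxidation enzymes Decr1 (-0.72 ± 0.13) and Ech1 (-0.60 ± 0.13), the synthetase Acsl1 (-0.53 ± 0.10) and the fatty acid transporter Cd36 (-0.65 ± 0.14) fell. Of 43 TCA cycle and oxidative phosphorylation genes, 1 rose and 7 fell (1 and 8 adjusted over the list alone, 0 and 29 under median scaling). TCA cycle genes as a list had adjusted p = 0.00820, and adjusted p = 0.266 with an estimated correlation. Idh2 (-0.98 ± 0.17), Ndufv1 (-0.56 ± 0.12) and Cox6c (-0.60 ± 0.15) fell and Ppargc1b rose (0.60 ± 0.17, its call lost in 11 of 23 alternative fits). Atp2a2 was at -0.07 ± 0.08 (adjusted p = 0.548), and above 0 under median scaling and in the series matrix values. Myh6 was at 0.14 ± 0.09 (adjusted p = 0.290, passing in 1 of 23 alternative fits), and both lay near the upper end of the range.

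Xcl1, a lymphocyte chemokine (at least 1.62-fold lower), and Klre1, a natural killer cell receptor (at least 1.54-fold lower), were detected on 0 of 6 ligated and 6 of 6 sham arrays. Nkg7, a cytotoxic granule protein, fell 2.51-fold (-1.33 ± 0.20). Of 5 T lymphocyte markers, 0 rose and 2 fell (0 and 4 adjusted over the list alone, 0 and 4 under median scaling). They did not pass as a list in camera, with adjusted p = 0.0787, and adjusted p = 0.318 with an estimated correlation. They passed in fry (adjusted p = 0.00497), which does not compare them with other genes. The falls were in the chemokine Ccl5 (-1.26 ± 0.19) and perforin, Prf1 (-0.55 ± 0.12). The interferon-induced chemokine Cxcl11 fell as well (-1.15 ± 0.19). Other large falls were in Fam81a (3.02-fold, detected on 2 of 6 ligated and 6 of 6 sham arrays) and P2ry1, an ADP receptor (2.49-fold, detected on 4 of 6 ligated and 6 of 6 sham arrays). Slc46a3, a lysosomal transporter, fell 2.54-fold and Efemp1, a fibulin, 2.41-fold, both detected on 3 of 6 ligated and 6 of 6 sham arrays.

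By probe, 1252 of 8351 passed in limma, 610 up and 642 down (48.7% up). Median scaling moved the median of all probes to -0.47 and gave 4710 calls, 1.72% of them up. Before scaling, the brightness of the ligated arrays differed from that of the sham arrays by a similar -0.520 log2 units. Array weights gave 2106, leaving out ligated replicate 3 or 5 or sham replicate 1, 2, 3 or 4 gave between 676 and 834, and array brightness in the fit left 3, none of them in a gene named here. A spread shared by all 6 groups lost the calls of Timp1 and Prf1.

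**Figure D4:**
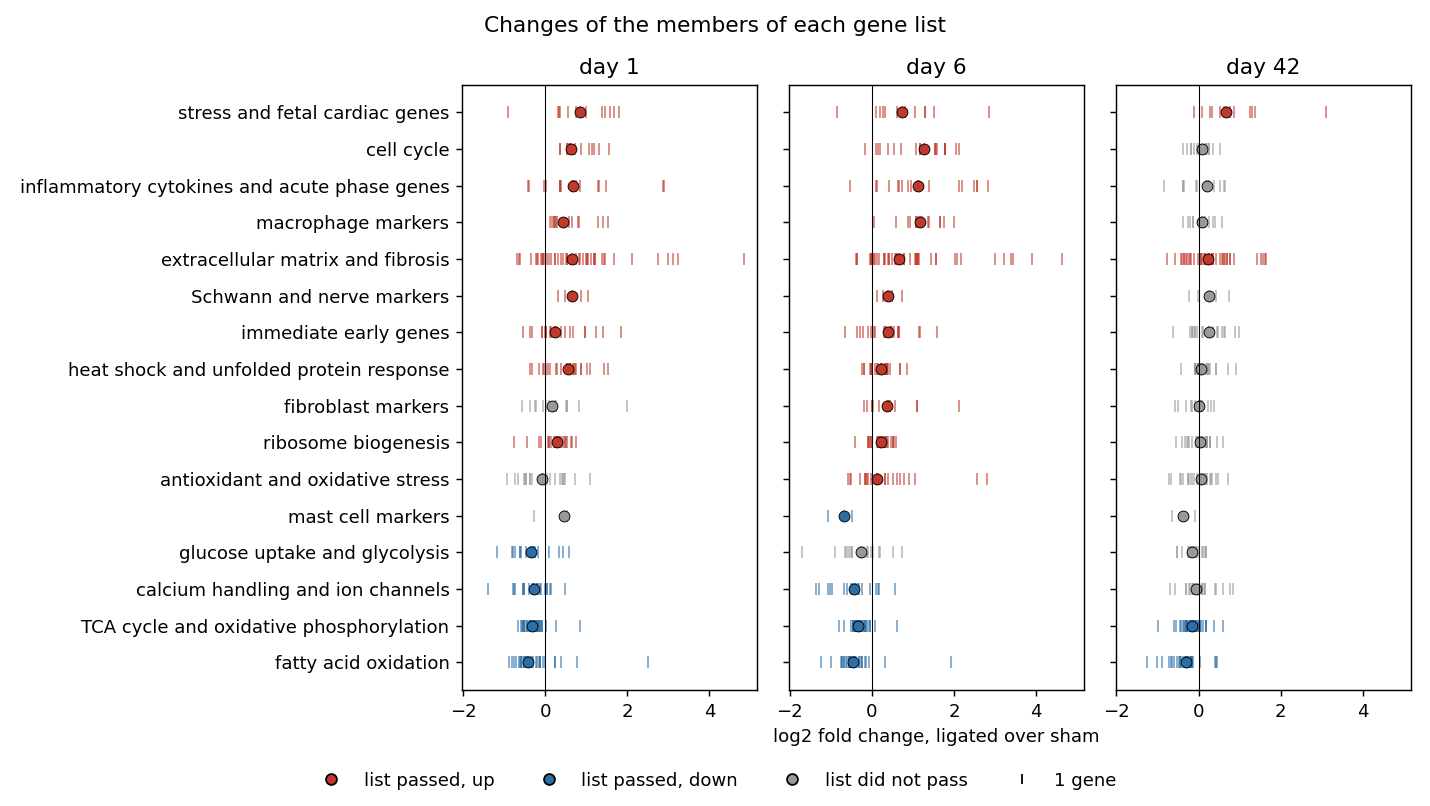
Each tick is the log2 fold change of ligated over sham (x axis) of a gene in the list named on the y axis, with a dot at the list's median, red or blue where the list passed the test with the preset correlation and grey where it did not or was not tested. The median of the stress and fetal cardiac genes was 0.85, 0.74 and 0.67 at days 1, 6 and 42 and that of fatty acid oxidation -0.42, -0.47 and -0.30, signs that held under each scaling, while the matrix median at day 42 turned from 0.23 to -0.27 under median scaling.

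The ligation effect was also compared between days, as the ligated minus sham difference of the later day minus that of the earlier one. From day 1 to day 6 the effect on Hmox1 grew by 2.21 ± 0.47 (adjusted p = 0.0163) and that on Lbp by 2.10 ± 0.35 (adjusted p = 0.00145). The effect on the matricellular protein Ccn3 went from -0.82 at day 1 to 1.12 at day 6, a difference of 1.95 ± 0.32. The differences were 1.93 ± 0.42 for complement C4b and 1.83 ± 0.34 for the Wnt antagonist Sfrp2. Sfrp2 was detected on 1 of 6 ligated and 1 of 6 sham arrays at day 1 and on 5 of 5 and 2 of 6 at day 6, so that its size rests on levels mostly at background. The effect on the leukotriene receptor Cysltr1 was lower at day 6 (adjusted p = 0.00555). It has no exact size, as it was detected on 6 of 6 ligated arrays at day 1 and on 0 other arrays of the 2 days. Between days 6 and 42 the effect on Reg3b changed by -4.88 ± 0.83 (adjusted p = 0.00103) and that on Spp1 by -4.74 ± 1.26 (adjusted p = 0.0207). The changes were -2.99 ± 0.54 for Cthrc1, -2.93 ± 0.47 for Hmox1 and -2.90 ± 0.79 for Ccl2. Cthrc1 was detected on 2 of 6 ligated and 1 of 6 sham arrays at day 42, Spp1 on 3 of 6 and 4 of 6, and Ccl2 on 5 of 6 and 4 of 6. The effect on the protease-like Prss35, detected on 0 arrays at day 42, was lower at day 42 with no exact size (adjusted p = 0.00141). Of the fixed genes, Postn changed by -2.69 ± 0.59 and Timp1 by -2.24 ± 0.52. Between days 1 and 42 the effect on Spp1 changed by -4.94 ± 1.23 (adjusted p = 0.0204) and that on Ccl2 by -2.95 ± 0.77. The values were -2.70 ± 0.81 for Reg3b, -2.49 ± 0.51 for Timp1 and -2.29 ± 0.57 for Postn. The effect was also lower at day 42 on Angptl4 (adjusted p = 0.0163) and the lipid kinase Pik3c2g (adjusted p = 0.0226), with no exact sizes. Angptl4 was detected on 0 of 6 sham arrays at day 1 and on 0 arrays at day 42, and Pik3c2g on 0 of 6 ligated arrays at day 42. For Nppa the difference was 1.47 ± 0.74 from day 1 to day 6 (adjusted p = 0.392) and 1.71 ± 0.72 from day 1 to day 42 (adjusted p = 0.117). For Nppb it was 0.96 ± 0.32 from day 1 to day 42 (adjusted p = 0.0541).

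Between days 1 and 6 the effect differed for 75 of 8711 probes (20 higher and 55 lower on the later day). It differed between days 6 and 42 for 671 of 8859 (342 and 329), and between days 1 and 42 for 769 of 8763 (404 and 365). Under median scaling these were 93 (7 higher and 86 lower), 543 (26 and 517) and 4684 (33 and 4651), with the median of all probes moved to -0.27, -0.38 and -0.67. Array weights gave 986, 439 and 2507, no detection filter 36, 475 and 460, and a replicate block 35, 367 and 565. Leaving out single arrays took the first count to 131 (ligated day 1 replicate 6) or to between 29 and 49 (ligated day 1 replicates 1 and 4, sham day 1 replicates 3, 5 and 6, sham day 6 replicate 6). It took the second to 410 and 390 (ligated day 6 replicates 1 and 2). The third went to between 183 and 505 (ligated day 1 replicates 1, 3 and 4, sham day 1 replicates 1 and 3, ligated day 42 replicate 3, sham day 42 replicate 1).

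Across probes, the changes of days 1 and 6 had a Pearson correlation of 0.667 (jackknife SE 0.128). It was 0.334 (SE 0.121) for days 6 and 42 and 0.381 (SE 0.0937) for days 1 and 42. Probes are not independent replicates. Days 1 and 6 shared 224 rises (chance gives 55.4) and 246 falls (77.0). Days 6 and 42 shared 73 rises (28.1) and 120 falls (38.9). Days 1 and 42 shared 207 rises (73.3) and 218 falls (97.9). Of 7732 probes tested on every day, 48 rose and 77 fell on all 3 days. Nppa, Ankrd23, Thbs4, Ltbp2, Timp1, Tgfb2, Ccn2, Col8a1, Enah, Flnc, Mybpc2, Rnd1 and Akip1 were among those that rose, and Apln, Kcnk2, Fam81a, Gpt and Klre1 among those that fell.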

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

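The tests of the cytotoxic lymphocyte transcripts, of the weak response of ligated replicate 2 at day 1 and of BeadChip position were chosen only after the results they address were seen, as was the fit with array brightness.

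The first pattern is that the 1252 probes called at day 42 came with ligated arrays dimmer than the sham arrays, 206 against 293 intensity units. As to brightness, its slope within the groups predicted 27.8% of the summed change of the called probes (20.6% to 31.5% with each array left out). This is under the 50% set in advance for a main source. As to position on the BeadChip, the day 42 changes of 1199 called probes were correlated with the day 6 changes blocked on position. At day 6 both operations lie in both sets of positions. The correlation was 0.497 (0.406 to 0.594 with each array left out), so part of the change was shared with day 6. How much of the rest comes from position cannot be told, since position and operation coincide at day 42. With brightness in the fit, the median change of the called probes went from 0.58 (median SE 0.14) to 0.41 (median SE 0.23) and 97.3% kept their sign, but the smaller change and larger error left 3 calls, in Dusp3, Map1b and a probe with no symbol, named after their values were seen. Part of the change may come from brightness, in a share that the data cannot bound. Brightness at day 42 ranged from 161 to 273 intensity units in the ligated and from 259 to 348 in the sham arrays. It thus almost follows the operation. An effect of the ligation on the changes remains a hypothesis.

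A second pattern is lower levels of transcripts of cytotoxic lymphocytes in the ligated ventricles at day 42, seen first in Nkg7, Klre1, Xcl1 and Ccl5. A list written after those were seen had 6 other measured members at day 42, of which 4 fell. The median change of the 6 was -0.74, and 0.01% of 10000 random lists matched on level alone were as low. The members of the random lists were drawn independently, whereas genes of 1 cell type vary together. The list was also written after related genes were seen to fall on the same arrays. That share is therefore no measure of support. Gzmc, Klrd1 and Klrb1a were detected on 2 of 6 ligated and 6 of 6 sham arrays, and S1pr5 on 1 and 4. The median is thus no exact size. Prf1 and Ccl5 also stand in the T lymphocyte list, Fcgr3a is also made by macrophages (-0.07, adjusted p = 0.887), and the most abundant members went from log2 levels of 10.1 to 8.86 (Ccl5) and 8.19 to 6.86 (Nkg7). Against array brightness, the 6 members of that list measured at day 1 (Gzmk in place of S1pr5) had a median of -0.51 (-0.58 to -0.38 with each array left out), when the ligated arrays were the brighter ones. At days 1 and 42 BeadChip position coincides with the operation. At day 6, with both operations in both sets of positions, the 7 measured members had a median of -0.62 (-0.96 to -0.41 with each array left out). Of these, 6 were below 0 and 2 fell, and Fcgr3a was at 0.90. The lower levels were thus not particular to day 42. Less blood in the ligated ventricles cannot be told apart from fewer cytotoxic lymphocytes or lower expression per cell. The reason is that only 1 of 6 erythroid probes, Hbb-b1, lay clear of the floor and of the upper end of the scanner range. At day 42 its ligated minus sham difference lay 0.505 above that of the 6 members (two-sided exact permutation p = 0.182) and 0.757 above that of all 10 (exact p = 0.0455). All 6 erythroid probes lay 0.834 and 1.09 above them (exact p = 0.0195 and 0.00866). The 10 include the 4 genes first seen through their fall, so their larger difference follows in part from that choice.

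The third pattern is a weak response of ligated replicate 2 at day 1, whose score was 0.372 on an axis from 0 at the sham mean to 1 at the mean of the other ligated arrays, over probes chosen without it. Against a mislabelled sham sample, the sham arrays scored between -0.0193 and 0.112, and the other ligated arrays between 0.673 and 1.33. Against array brightness as the main source, the slope among the other 5 ligated arrays accounted for 36.2% of its gap (31.7% to 41.5% with each of them left out), and the ligated replicates 5 and 6, no brighter than replicate 2, scored 0.673 and 0.711, although the 3 brightest ligated arrays had the 3 highest scores. Without replicate 2 the day 1 count was 2934 in place of 2368, and at day 6 the ligated replicates 3 and 4 also scored low, 0.492 and 0.550 against 1.08 to 1.35 for the other 3. Brightness may account for part of the gap, and a milder constriction in such animals is a hypothesis that no measurement here tests.

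Chance is unlikely for the probe counts of the days: 1 of 100 splits of the arrays, the real one, gave 2368 at day 1 (highest other 1242), 1 gave 958 at day 6 (highest other 15) and 1 gave 1252 at day 42 (highest other 924). At days 1 and 42 the real split is also that of BeadChip position, and at day 42 almost that of brightness. The splits cannot separate these from the operation there. For the numbers of gene lists chance cannot be excluded, with 14 of 100 splits giving at least the real 13 at day 1 (highest other 17), 6 at least 15 at day 6 (highest other 17) and 49 at least 4 at day 42 (highest other 10).

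The ligation effect differed between days for 75 probes (days 1 and 6), 671 probes (days 6 and 42) and 769 probes (days 1 and 42). Shuffling ligated and sham within each day reached as many in 4, 1 and 1 of 100 shuffles, the real one included. The highest other counts were 536, 448 and 150. Chance is thus unlikely for days 6 and 42 and for days 1 and 42. For days 1 and 6 it is not excluded, since a shuffle gave several times the real count. What that shuffle reflects was not tested. The correlations of the effect between days of 0.667, 0.334 and 0.381 (days 1 and 6, 6 and 42, 1 and 42) were reached in 1, 4 and 2 of 100 shuffles. The highest others were 0.581, 0.377 and 0.426. That makes chance unlikely for days 1 and 6. It does not exclude chance for the other pairs, where shuffles gave higher values.

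The genes with the largest fitted differences of effect from day 1 to day 6 were Hmox1 (2.21), Lbp (2.10), Ccn3 (1.95), C4b (1.93), Sfrp2 (1.83) and Cysltr1 (-1.81). From day 6 to day 42 the values were Reg3b (-4.88), Spp1 (-4.74), Prss35 (-3.10), Cthrc1 (-2.99), Hmox1 (-2.93) and Ccl2 (-2.90), and of the fixed genes Timp1 (-2.24) and Postn (-2.69). From day 1 to day 42 the values were Spp1 (-4.94), Ccl2 (-2.95), Angptl4 (-2.92), Reg3b (-2.70), Pik3c2g (-2.51) and Timp1 (-2.49), and of the fixed genes also Postn (-2.29). The values of Cysltr1, Prss35, Angptl4 and Pik3c2g are no exact sizes, since a group of each had 0 arrays that detected it. Those of Sfrp2, Cthrc1, Spp1, Ccl2 and Lbp rest in part on arrays that did not detect them. Single arrays stood apart from their group in 4 of 89 sets of values, where chance gives about 1 in 20. Sham day 1 replicate 4 had a median of 30 beads per probe, where the others had 39 to 42. Ligated day 42 replicate 1 had a median of 41 beads, where the others had 42. The log2 intensity of Atp2a2 was 15.3 on sham day 1 replicate 2, where the others lay between 15.57 and 15.69. The log2 intensity of Ankrd1 was 15.5 on ligated day 6 replicate 1, where the others lay between 15.88 and 15.96.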

How the results depend on the processing

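The fit with array brightness was chosen after the data had been seen, and all other alternatives before. Of the values of the named genes, 687 of 726 at day 1, 693 of 755 at day 6 and 476 of 559 at day 42 kept their direction and their side of the threshold across the alternatives, and 781 of 794, 656 of 704 and 594 of 624 with single arrays left out. Of the values of passing lists, 77 of 91, 86 of 105 and 23 of 28 did so, and of those of named differences 139 of 147. Under median scaling the counts were 132 at day 6, 4710 at day 42 and 4684 for days 1 and 42, and 7 lists passed at day 42. No detection filter gave 562 at day 6, 36 for days 1 and 6 and 460 for days 1 and 42, where more probes were tested, and a correlation of 0.272 for days 1 and 42. A spread shared by all 6 groups gave 1634 at day 6. Array weights gave 2106 at day 42, and 986, 439 and 2507 for days 1 and 6, 6 and 42, and 1 and 42. A replicate block gave 315 at day 6 and 35 and 367 for days 1 and 6 and 6 and 42. The labels do not state that replicate numbers pair the samples. The correlation within pairs after removing group means lay between -0.27 and 0.34. With so few pairs per day it cannot decide whether they do. An estimated correlation left 0, 1 and 0 lists at days 1, 6 and 42, and fry gave 8 at day 42. Array brightness in the fit gave 1199 at day 1, 1414 at day 6 and 3 at day 42. In the brightness fit the changes were smaller at days 1 and 42 while the errors hardly moved at day 1 and grew at day 42. The shifts of the median under median scaling at days 1 and 42 were close to the brightness differences of these days. Apart from that, the brightness fit and the filter, the cause was not tested.

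Leaving out single arrays gave between 1576 and 2934 probes at day 1 (1576 without ligated replicate 4), between 524 and 1189 at day 6 (ligated replicate 2 627, 5 524, sham replicate 1 590, 2 593, 4 597, 5 546, 6 541) and between 676 and 1772 at day 42 (ligated replicate 3 810, 5 834, sham replicate 1 736, 2 753, 3 676, 4 788). For lists the ranges were 11 to 13, 12 to 17 and 4 to 7, the last with 7 without ligated replicate 2 or sham replicate 4. Differences ranged from 29 to 131 for days 1 and 6 (ligated day 1 replicate 1 29, 4 47, 6 131, sham day 1 replicate 3 30, 5 45, 6 46, sham day 6 replicate 6 49), from 390 to 910 for days 6 and 42 (ligated day 6 replicate 1 410, 2 390) and from 183 to 1139 for days 1 and 42 (ligated day 1 replicate 1 273, 3 274, 4 183, sham day 1 replicate 1 460, 3 461, ligated day 42 replicate 3 505, sham day 42 replicate 1 372). Correlations ranged from 0.578 to 0.699, 0.272 to 0.403 and 0.336 to 0.412.

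The values of single genes that reversed were of fixed genes that had not passed. Under median scaling the matrix median at day 42 also turned below 0, and most calls rose at day 1 and fell at day 42. Median scaling gave 0.040 for Myh6 and 0.17 for Col3a1 at day 1, and 0.072 for Atp2a2 and -0.46 for Col1a1 at day 42. The series matrix gave Atp2a2 -0.046, 0.025 and 0.28 at days 1, 6 and 42. Array weights gave 0.13 for Col3a1 at day 1 and -0.095 for Col1a1 at day 42. Brightness gave 0.040 for Myh6 at day 1 and 0.023 for Atp2a2 at day 42. Without single arrays Col3a1 at day 1 ranged from -0.19 (without ligated replicate 4) to 0.15, and was 0.059 without ligated replicate 1, 0.025 without ligated replicate 2, 0.15 without sham replicate 4 and 0.0058 without sham replicate 5, and Col1a1 at day 42 ranged from -0.082 to 0.22 (without ligated replicate 6), and was -0.079 without ligated replicate 2, -0.0038 without ligated replicate 3 and -0.082 without sham replicate 2. The position block could not be fitted at days 1 and 42, where position and operation coincide.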

Other observations

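No test of the lists described here was chosen after its result was seen. Beyond the lists named in the comparisons, genes of vascular regulation and of other cell types changed singly. At day 1 Ace, the angiotensin converting enzyme, rose (1.17 ± 0.18) and Corin, the protease that activates atrial natriuretic peptide, fell (-0.89 ± 0.16). At day 6 the alpha adrenergic receptor Adra1b (adjusted p = 0.00551) and the endothelial nitric oxide synthase Nos3 (-1.40 ± 0.36, its call lost in 8 of 23 alternative fits) fell, and the prostacyclin synthase Ptgis rose at day 6 (0.56 ± 0.16, its call lost in 11 of 23 alternative fits) and day 42 (0.81 ± 0.21, its call lost under median scaling). The clock-linked repressor Nfil3 rose at day 1 (1.06 ± 0.16), while Bhlhe40 (-0.58 ± 0.16, its call lost under median scaling) and the nuclear receptor Nr1d1 (-0.66 ± 0.22, its call lost in 11 of 23 alternative fits) fell. Among smooth muscle genes Mustn1 (2.39 ± 0.45), the coactivator Myocd (0.60 ± 0.15) and Tagln (0.58 ± 0.15) rose at day 1. The call of Tagln was lost with array brightness in the fit and with a spread shared by all 6 groups. Myocd (0.62 ± 0.12) and the pericyte proteoglycan Cspg4 (0.79 ± 0.16) rose at day 42, both with their calls lost under median scaling. The mesothelial and epicardial genes Wt1 (-0.77 ± 0.17) and Gpm6a (-0.78 ± 0.19) fell at day 6, neither of them under median scaling. At day 1 the metallothionein Mt1 rose (1.08 ± 0.24, its call lost with a spread shared by all 6 groups). The peroxiredoxin Prdx6 fell at day 1 (-0.46 ± 0.09, its call lost under median scaling). Egr1, an immediate early transcription factor, rose at day 42 (0.99 ± 0.20), and the adipocyte water channel Aqp7 fell at day 42 (-0.85 ± 0.17).

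Some lists passed camera with the preset correlation on no day. As members that rose and that fell at days 1, 6 and 42, they gave these counts. For the adult contractile apparatus they were 1 and 2 of 18, 1 and 0 of 18, 0 and 2 of 18 (1 and 2, 1 and 0 and 0 and 2 adjusted over the list alone, list adjusted p = 0.446, 0.388 and 0.787). For neurohormonal and vasoactive genes they were 3 and 5 of 18, 1 and 3 of 20, 1 and 1 of 17 (4 and 6, 4 and 5 and 1 and 1 adjusted over the list alone, list adjusted p = 0.808, 0.741 and 0.893). For glucocorticoid-responsive genes they were 3 and 0 of 17, 1 and 0 of 17, 1 and 0 of 15 (3 and 0, 1 and 0 and 0 and 0 adjusted over the list alone, list adjusted p = 0.305, 0.211 and 0.464). For the circadian clock they were 1 and 2 of 9, 0 and 0 of 9, 0 and 0 of 9 (1 and 2, 0 and 0 and 0 and 0 adjusted over the list alone, list adjusted p = 0.747, 0.745 and 0.998). For hypoxia-responsive genes they were 1 and 3 of 16, 1 and 1 of 16, 1 and 1 of 16 (1 and 3, 2 and 2 and 1 and 1 adjusted over the list alone, list adjusted p = 0.446, 0.927 and 0.769). For the interferon response they were 0 and 3 of 26, 1 and 1 of 26, 0 and 2 of 25 (0 and 3, 1 and 1 and 0 and 1 adjusted over the list alone, list adjusted p = 0.556, 0.505 and 0.0809). For T lymphocyte markers they were 0 and 2 of 4, 0 and 0 of 4, 0 and 2 of 5 (0 and 3, 0 and 0 and 0 and 4 adjusted over the list alone, list adjusted p = 0.298, 0.388 and 0.0787). For erythroid markers they were 0 and 2 of 7, 0 and 0 of 8, 0 and 0 of 6 (0 and 2, 0 and 0 and 0 and 0 adjusted over the list alone, list adjusted p = 0.794, 0.738 and 0.787). For endothelial markers they were 1 and 1 of 13, 0 and 0 of 11, 0 and 1 of 13 (0 and 0, 0 and 0 and 0 and 1 adjusted over the list alone, list adjusted p = 0.794, 0.709 and 0.675). For smooth muscle and pericyte markers they were 4 and 1 of 6, 3 and 0 of 6, 2 and 0 of 6 (4 and 2, 3 and 1 and 2 and 1 adjusted over the list alone, list adjusted p = 0.191, 0.388 and 0.117). For atrial cardiomyocyte markers they were 2 and 2 of 6, 1 and 0 of 5, 2 and 0 of 5 (2 and 2, 1 and 0 and 2 and 0 adjusted over the list alone, list adjusted p = 0.945, 0.292 and 0.0809). For adipocyte markers they were 0 and 1 of 4, 0 and 0 of 4, 0 and 2 of 4 (0 and 2, 1 and 2 and 0 and 2 adjusted over the list alone, list adjusted p = 0.446, 0.709 and 0.0809). For skeletal muscle markers they were 1 and 1 of 3, 2 and 0 of 4, 1 and 1 of 4 (2 and 1, 2 and 1 and 1 and 1 adjusted over the list alone, list adjusted p = 0.208, 0.0679 and 0.893). Neutrophil and mesothelial markers had 2 measured genes each and B lymphocyte markers 0 at day 1 and 1 on the later days, too few for a test, and the only changes were falls of 2 mesothelial genes at day 6 and 1 at day 42, as many as adjusted over the list alone. On the array the adult contractile list held Dbi, matched to a written symbol through an alias, and neither Ttn nor Tcap. Its counts may thus include a gene outside the contractile apparatus.

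Lists that passed on another day gave values as well. At day 1 the members that rose and fell were for antioxidant genes 4 and 7 of 23 (4 and 9 adjusted over the list alone, list adjusted p = 0.739), for fibroblast markers 1 and 1 of 14 (1 and 1 adjusted over the list alone, list adjusted p = 0.305) and for mast cell markers 0 and 0 of 3 (0 and 0 adjusted over the list alone, list adjusted p = 0.446). At day 42 they were for inflammatory genes 1 and 0 of 14 (0 and 0 adjusted over the list alone, list adjusted p = 0.675), for macrophage markers 0 and 0 of 12 (0 and 0 adjusted over the list alone, list adjusted p = 0.936), for the cell cycle 1 and 0 of 15 (0 and 0 adjusted over the list alone, list adjusted p = 0.654), for calcium handling and ion channels 2 and 2 of 23 (2 and 2 adjusted over the list alone, list adjusted p = 0.893), for immediate early genes 3 and 0 of 21 (3 and 0 adjusted over the list alone, list adjusted p = 0.0847) and for heat shock and unfolded protein response 4 and 0 of 26 (4 and 0 adjusted over the list alone, list adjusted p = 0.0809). On the same day they were for glycolysis 0 and 1 of 19 (0 and 0 adjusted over the list alone, list adjusted p = 0.358), for ribosome biogenesis 0 and 1 of 26 (0 and 0 adjusted over the list alone, list adjusted p = 0.787), for antioxidant genes 1 and 3 of 23 (1 and 3 adjusted over the list alone, list adjusted p = 0.893), for fibroblast markers 0 and 1 of 14 (0 and 0 adjusted over the list alone, list adjusted p = 0.893), for Schwann and nerve markers 1 and 0 of 5 (2 and 0 adjusted over the list alone, list adjusted p = 0.199) and for mast cell markers 0 and 0 of 2 (0 and 1 adjusted over the list alone). Under median scaling the members that rose and fell at day 42 were 0 and 13 of 26 for heat shock and unfolded protein response, 0 and 16 of 26 for ribosome biogenesis and 0 and 13 of 19 for glycolysis. They were 0 and 13 of 23 for antioxidant genes, 0 and 19 of 25 for the interferon response and 1 and 7 of 21 for immediate early genes. The fry test passed 15, 14 and 8 lists at days 1, 6 and 42. Of the lists that camera with the preset correlation passed on no day, fry passed hypoxia-responsive genes at day 1 (adjusted p = 0.00984). It passed smooth muscle and pericyte markers at days 1 (0.00525) and 42 (0.0081), and skeletal muscle markers at days 1 (0.000279) and 6 (0.00106). It also passed atrial markers at days 6 (0.0167) and 42 (0.0103), and T lymphocyte (0.00497) and adipocyte markers (0.0089) at day 42. The median, the mean and the camera test of a list differed in sign for glucocorticoid-responsive genes and atrial markers at day 1, the interferon response at day 6, and the adult contractile apparatus, antioxidant genes, calcium handling, fibroblast markers and the circadian clock at day 42, none of which passed.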
